A study of Mus musculus with 17 samples.

How the data were processed

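RNA-seq libraries of mouse bile duct from a study of extrahepatic cholangiocarcinoma were analysed from the authors' table of read counts per gene. The deposited count values are whole, not normalized counts of reads per gene. The submitters' processing notes name STAR 2.6.1c, featureCounts and edgeR 3.40.2 and the mouse build mm10, without the role or order of each tool. The annotation release, the strand setting and the version of featureCounts are not given in the sources used here, so counts of overlapping and antisense genes and of near-identical copies are uncertain. The table gave 43346 genes with position, length, name and biotype. A further 17 columns of per-sample values in another unit were not used here. All coordinates are those of the table, on mm10.

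Each count column was named by a code and a running number, and no name matched a sample title. The columns could therefore be tied to the single group, bile duct, but not to single samples, and libraries are named here by their columns. With no groups in the labels, no comparison between conditions was made. Library totals were 16400556 to 24152314 counts. Shares of counts in a library carry 95% Wilson intervals, which cover counting error only, because reads without molecular identifiers are not independent molecules.

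Genes were kept with edgeR 4.0.16 filterByExpr and an intercept-only design (15795 genes), normalized with TMM factors, and expressed as log2 CPM with a prior count of 2. CPM refer to the counts of the kept genes scaled by the TMM factor, also for genes that were not kept, such as most acinar and Y-linked genes, so such a gene's CPM can exceed its share of all counts. RPKM were computed from the counts and the table's gene lengths. Variable genes were sought in R 4.3.3 with an intercept-only edgeR quasi-likelihood fit with trended dispersion and a robust prior: each gene's quasi-dispersion over the trend was tested with a 1-sided F test, Benjamini-Hochberg adjusted p below 0.05. As first written, the test used each gene's own prior degrees of freedom. On simulated counts that form recovered 0% of 200 varied genes, and it was replaced by the largest prior degrees of freedom over all genes (3.84 here) after the real counts had been seen. With the largest prior degrees of freedom, the test recovered 99.5% of 200 genes with an added log2 SD of 1 where dispersions were even. In these simulated counts it made 7 false calls among 15795 genes, and the largest prior degrees of freedom were 2934. Where dispersions were uneven, with 4.23 prior degrees of freedom, it recovered 0%.

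Gene lists were fixed before the data were examined: 36 lists with 385 genes, all matched to the table, 2 of them by identifier. The cell type lists were cholangiocyte, gastric and gland mucin, intestinal epithelium, hepatocyte, pancreatic acinar, pancreatic islet, fibroblast and matrix, smooth muscle, striated muscle, endothelial, macrophage, neutrophil, T cell, B and plasma cell, nerve and Schwann cell, adipocyte, mesothelial and erythroid. The pathway lists were proliferation, MAPK output, p53 target, hypoxia and glycolysis, EMT, TGF-beta target, YAP target, Wnt target, Notch, Hedgehog, interferon response, inflammatory cytokine, NRF2 target and bile acid handling. Immediate early and heat shock lists stood for tissue handling, and cholangiocarcinoma driver and sex-linked lists were used for levels. A list with at least 5 tested members received a score, the mean log2 CPM of its members, which 29 lists did. Named are the 20 genes with the highest median CPM; up to 25 variable genes by SD, of which there were none; in each list the 3 members with the highest median RPKM and the 2 with the largest SD of log2 CPM; and the driver and sex-linked genes. The rule had named FPKM, for which computed RPKM stood in. Islet genes, Prss2 and genes that differ between codes were named after their values had been seen.

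Structure was described by principal components of the 500 most variable genes, and a mixture of normal distributions on the first component (mclust 6.1.1, BIC gain above 6) decided whether libraries formed separate sets. Correlations of list scores were then computed within the sets of 11 and 6 libraries only, with Pearson's r and Spearman's rho, 2-sided p-values from 100000 permutations or, in the set of 6, all 720 orders, and Benjamini-Hochberg adjustment over all pairs. A pair passed when both adjusted p-values were below 0.05. Coherence of a list was the mean correlation between its members, set against 10000 random lists matched on expression. On simulated libraries 5 of 5 planted lists and the pair planted in the set of 11 were recovered, with 1 of 24 other lists and 0 of 377 other pairs called. The planted pair was very strong (r = 0.999), and the simulated libraries were drawn without resemblance within codes. These counts therefore do not show recovery of weaker relations or the rate of false calls among libraries that share a code.

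After the column names had been seen, tests between the 6 codes were added: an edgeR quasi-likelihood F test with 5 degrees of freedom, permutations of the codes over the libraries for list scores, and correlations of deviations from the code means over all 15552 orders within codes. On simulated counts the code test recovered 74% of 100 genes changed 2-fold in 1 code and 99% of 100 changed 4-fold, with 9 false calls among 15795 genes. These counts were drawn with even dispersions only, so the code test's recovery and false calls under uneven ones were not measured. Alternatives were DESeq2 1.42.0 and limma 3.58.1, DESeq2 size factors, library totals, other filters and prior counts, other list scores, and leaving out each library. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for lists and permutations. The levels of some genes of the fixed lists are not reported here.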

Results

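RNA from mouse bile duct was sequenced in a study of extrahepatic cholangiocarcinoma, a cancer of the bile ducts outside the liver. The series held 17 samples, all labelled as bile duct, and the labels gave no condition, genotype, treatment, age or sex that would set samples apart. No groups could therefore be compared, and each measurement is given per library or as its median and range over the 17 libraries. The labels also do not say whether the samples came from separate animals, so p-values refer to these libraries only. Part of the spread between libraries may be technical. Xist, a sex-linked RNA, stood at 668 to 1499 CPM in 12 libraries and at 0.650 to 5.92 CPM in 5. Y-linked genes had counts in those 5 only, which argues against technical spread alone for the sex-linked genes.

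Read counts were given for 43346 genes in 17 libraries. Library totals ran from 16400556 to 24152314 counts, with a median of 17886041, and between 20620 and 23036 genes had at least 1 count in a library. Protein-coding genes held 96.2% of all counts. The 37 mitochondrial genes in the table were at 0 in every library, so no mitochondrial share was available as a measure of RNA quality. A library was named in the table by a code and a running number, such as R62848_1. The table held 6 codes, of which 5 covered 3 libraries each and 1, R63494, covered 2. The meaning of the codes is not given in the sources used here, and these names matched no sample title.

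The most abundant genes by median CPM, which is not adjusted for gene length, included several that encode secreted or mucosal defence proteins. Dmbt1, which encodes a mucin-like scavenger receptor of mucosal surfaces (ENSMUSG00000047517, mm10 chromosome 7, from 131032076 to 131121626), was the most abundant gene by median. It took 2.88% of the counts in the library where it was lowest and 5.50% where it was highest. Clu, the secreted chaperone clusterin (chromosome 14, from 65968483 to 65981548), followed with 1.44% to 2.52% of counts. Next in median abundance stood the complement component C3 (median 6438 CPM), the polymeric immunoglobulin receptor Pigr, which carries IgA across epithelia (6376 CPM), and the iron-binding defence proteins Lcn2 (6254 CPM) and Ltf (5894 CPM). The immunoglobulin genes Igha (4328 CPM) and Igkc (3173 CPM) were also among the 20 most abundant genes. Among these 20 genes Igha varied most, from 1362 CPM in R63500_2 to 7752 CPM in R63496_3, whereas Lcn2 stayed between 4993 and 7986 CPM. The rest of the 20 were Eef1a1, Eef2, Krt8, Duox2, Atp1b1, Col3a1, Hsp90ab1, Plet1, C4b, Ftl1, Fth1 and Ly6e. The 10 most abundant genes of each library together held 7.98% to 15.7% of its counts.

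Markers of cholangiocytes, the epithelial cells that line bile ducts, were detected in all 17 libraries. Their list score, the mean log2 CPM of the 15 tested members, ran from 8.49 in R62848_2 to 8.88 in R63496_2. This 1.31-fold range was the narrowest among the 29 scored lists. The score averages 15 members with a mean correlation of 0.208, so its narrow range does not show that the single genes were steady. The median SD of these members stood at percentile 81.24 of random lists matched on expression. In tests added after the column names had been seen, the score differed between codes (permutation, adjusted p = 0.00693). So did all 15 tested members in edgeR's quasi-likelihood test. The keratins Krt8, Krt19 and Krt18 had median levels of 2073, 1386 and 963 CPM. Krt19 lay between 1003 and 1684 CPM. The members that varied most were Spp1, which encodes osteopontin, from 392 CPM in R63494_1 to 2147 CPM in R63496_2, and the tight junction gene Cldn4, from 22.8 CPM in R63494_1 to 244 CPM in R63500_2.

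Gastric and gland mucin genes were present at levels that differed between libraries by up to 2.90-fold on the list score. Tff2, a trefoil peptide secreted with gland mucus, had a median of 342 CPM and reached 944 CPM in R62850_1. The gland mucin Muc6 spanned 5.96 CPM in R63496_3 to 302 CPM in R63494_2, and Gkn3 spanned 0.339 to 37.2 CPM. The 3 R62850 libraries and the 2 R63494 libraries had the highest scores, 5.41 to 5.52 and 5.57 to 5.61, against 4.08 to 5.13 in the other 12. These 5 libraries also had heat shock scores of 8.27 to 9.10, above those of the other 12 (6.31 to 7.64) except R63500_2 (8.65). Within codes the mucin and heat shock scores had an r of -0.365 (exact p = 0.371, adjusted p = 0.801) and a rho of -0.108 (exact p = 0.746), with r = -0.604 without the 2 farthest libraries. Of the intestinal epithelial markers, Olfm4 was abundant (median 1567 CPM, from 950 to 2251 CPM), whereas the goblet cell mucin Muc2 had a median of 2.20 CPM and a maximum of 36.2 CPM in R62850_1. Hepatocyte markers were low apart from Ttr, the thyroid hormone carrier transthyretin (median 411 CPM): the albumin gene Alb lay between 0.921 and 31.8 CPM. The genes of bile acid handling had scores between 3.31 and 4.31, and the export pump Abcc3 was their most abundant member (median 307 CPM).

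Digestive enzyme genes of the pancreatic acinar cell were higher in each library of 1 code, R62850, than in any other library, for all 11 enzyme genes of the list. Together, 11 of these genes took 0.618% of the counts in R62850_1 (95% Wilson interval 0.614% to 0.621%), 2.48% in R62850_2 (2.47% to 2.48%) and 11.96% in R62850_3 (11.94% to 11.98%). In the other 14 libraries they took 0.00412% to 0.0155%. These intervals cover counting error only. Ctrb1, a chymotrypsinogen gene (chromosome 8, from 111686510 to 111691010), stood at 1565, 6259 and 36476 CPM in R62850_1, R62850_2 and R62850_3, and its highest level elsewhere was 9.75 CPM. The elastase gene Cela2a reached 20533 CPM in R62850_3 and 6.66 CPM at most outside that code. Cela1, another elastase gene, was the exception to such low levels elsewhere: it stood at 766, 2581 and 14399 CPM in the R62850 libraries and reached 146 CPM outside them, with a lowest level of 39.6 CPM. Prss2 belongs to a family of near-identical trypsinogens whose reads may be split between copies. The insulin genes Ins1 and Ins2 had no counts outside R62850 and were also highest in R62850_3, far below the enzymes. Ins2 stood at 0.169, 0.164 and 3.22 CPM in R62850_1, R62850_2 and R62850_3, and Ins1 at 0, 0 and 2.26 CPM. Of the other islet hormone genes, Ppy reached 2.06 CPM in R62850_3 and at most 1.05 CPM in other codes, and Gcg and Iapp had no counts in R62850. The somatostatin gene Sst went the other way, at 13.5 and 17.2 CPM in R62850_1 and R62850_2, lower in R62850_3 and up to 16.3 CPM in other codes. The endocrine granule gene Chga was also lowest in R62850_3 within its code, at 6.42, 11.7 and 2.74 CPM, and reached 10.7 CPM in other codes. So were Chgb (3.16, 2.89 and 1.10 CPM) and Pcsk2 (2.20, 1.58 and 0.892 CPM), and Neurod1 had no counts in R62850_3. Because filterByExpr kept a gene only if it was counted in most libraries, 3 acinar genes entered the test, and neither this list nor the islet, striated muscle, adipocyte and mesothelial lists received a score.

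**Figure D1:**
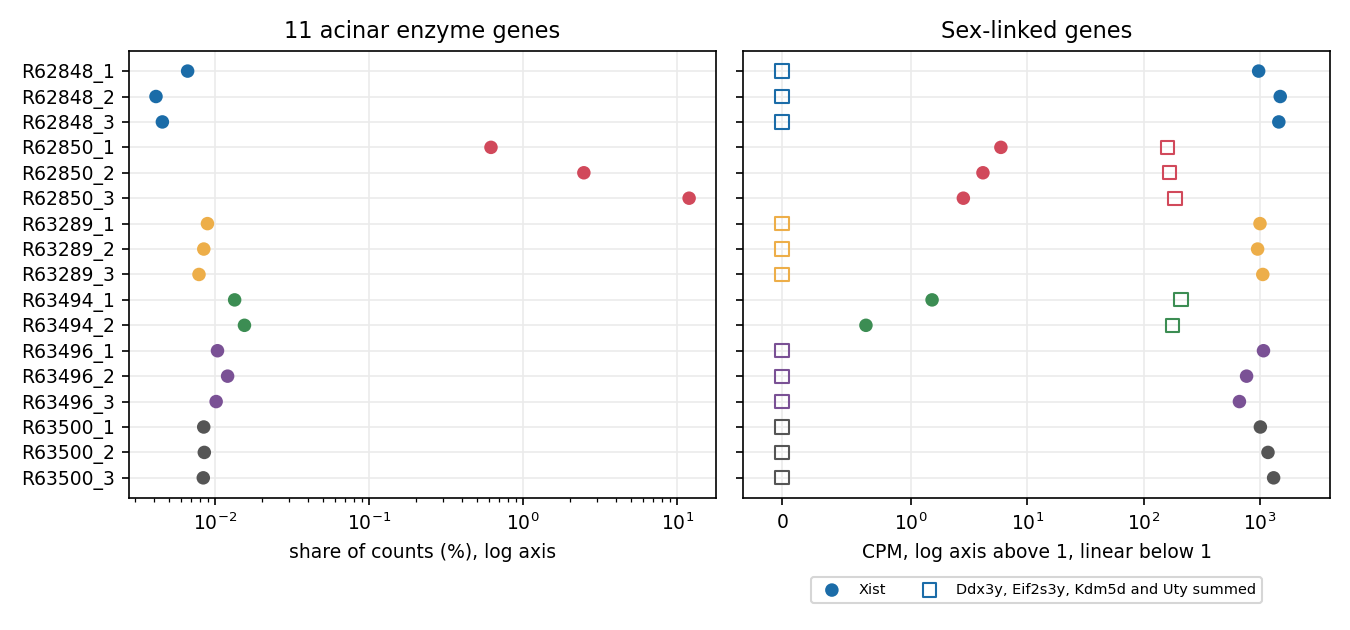
Share of counts taken by 11 pancreatic acinar enzyme genes (left, percent on a log axis) and CPM of Xist and of the summed Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty (right, log axis above 1), with a point per library coloured by its code. The acinar share is 0.618% to 11.96% in the R62850 libraries and at most 0.0155% in the others, and the Y-linked genes are at 160 to 210 CPM in the R62850 and R63494 libraries and at 0 in the rest.

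Sex-linked transcripts divided the libraries without overlap. Xist, the noncoding RNA of the inactive X chromosome (X chromosome, from 103460375 to 103483217), stood at 668 to 1499 CPM in 12 libraries, all those of R62848, R63289, R63496 and R63500, and at 0.650 to 5.92 CPM in the 5 libraries of R62850 and R63494. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 160 to 210 CPM in these 5 libraries and had no counts in the other 12. This division followed the codes, and the labels give the sex of no sample. The same 5 libraries had the highest gastric and gland mucin scores and, apart from R63500_2, the highest heat shock scores. The sex-linked pattern therefore cannot be told apart from other differences between these 2 codes and the rest.

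Genes of fibroblasts and extracellular matrix spanned a 3.50-fold range of the list score. Col1a1 lay between 431 CPM in R63494_1 and 3260 CPM in R63500_2, Col3a1 between 758 and 3663 CPM, and Fn1, which encodes fibronectin, between 504 and 4588 CPM. The highest score outside R62848 and R63500 was 8.30, the R63500 libraries had 8.82 to 9.11 and the R62848 libraries up to 9.05, and the 2 R63494 libraries had the lowest, 7.30 to 7.34. The libraries of R62848 and R63500 also had the highest scores of the endothelial list (5.32 to 5.84, against 4.76 to 5.22 in the other 4 codes), the hypoxia and glycolysis list (6.54 to 7.05, against 5.43 to 5.76), the EMT list of epithelial-to-mesenchymal transition genes (4.18 to 4.89, against 2.82 to 3.70), the TGF-beta target list (6.77 to 7.01, against 5.83 to 6.36) and the YAP target list (6.18 to 6.42, against 5.27 to 6.04). An example was Bnip3, a hypoxia-induced mitophagy gene, at 15.2 to 91.5 CPM. The p53 target scores (5.22 to 5.58, against 4.76 to 5.07) and erythroid scores (3.36 to 4.77, against 2.03 to 3.04) split the same way. Hedgehog scores did so narrowly (3.61 to 4.09, against 2.53 to 3.60). Smooth muscle genes stayed low, with Acta2 at 41.9 to 111 CPM, and striated muscle genes were near the floor, with the highest median, that of Mylpf, at 0.961 CPM. The nerve and Schwann cell score varied 1.66-fold. Of the adipocyte genes Cidec reached 12.3 CPM in R62850_2, and of the mesothelial genes Msln lay between 71.9 and 209.7 CPM.

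Immune genes varied most in the neutrophil and in the B and plasma cell lists. The neutrophil score ran from 5.96 in R63500_2 to 8.38 in R62848_2, a 5.33-fold range, with the calprotectin genes S100a8 at 70.0 to 469 CPM and S100a9 at 81.2 to 628 CPM. The B and plasma cell score had a 7.18-fold range, from 4.61 in R63500_2 to 7.46 in R63496_3, and Jchain, which joins IgA and IgM units, lay between 239 and 1924 CPM. Ighm reached 406 CPM in R62850_2 and was as low as 11.3 CPM in R63494_2. Macrophage scores lay between 4.90 and 6.28, with Lyz2 at 297 to 766 CPM. T cell genes were low, with scores of 1.76 to 3.01 and a Cd3e median of 7.16 CPM. Inflammatory cytokine scores varied 3.17-fold; Cxcl5, a neutrophil chemokine, was at 803 to 2213 CPM and the acute-phase gene Saa3 at 40.4 to 583 CPM. Interferon response scores lay between 2.84 and 4.04. Erythroid scores were highest in the 3 R62848 libraries, 4.67 to 4.77 against 2.03 to 3.63 elsewhere, where Hbb-bs reached 172 CPM. Haemoglobin genes took at most 0.0305% of counts, and their near-identical copies can exchange reads.

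Proliferation scores ran from 2.76 in R63494_2 to 4.27 in R63500_3, and Cdk1 reached 15.9 CPM in R63500_1. MAPK output genes, the feedback targets of the RAS pathway, had a 2.13-fold range, and the phosphatase gene Dusp6 lay between 40.1 and 104 CPM. The p53 target score had a 1.76-fold range, and Cdkn1a, which encodes the cell cycle inhibitor p21, spanned 15.2 CPM in R63496_1 to 119 CPM in R63500_2. Wnt target, Notch and Hedgehog list scores had ranges of 2.66-fold, 1.79-fold and 2.95-fold, and their members with the highest median RPKM, which adjusts counts for gene length, were Rnf43 at 8.56, Hes1 at 57.1 and Ptch1 at 5.20. NRF2 targets of the oxidative stress response were high, with scores of 7.01 to 7.61 and Gsta4 at 416 to 912 CPM. The median SD of their tested members stood at percentile 95.02 of random lists matched on expression. Their score differed between codes in the permutation test added after the column names had been seen (adjusted p = 0.0299).

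Heat shock genes, which encode chaperones induced by protein damage, showed a 6.94-fold range of the score. It was 9.05 to 9.10 in the 2 R63494 libraries, 8.27 to 8.46 in the 3 R62850 libraries and 8.65 in R63500_2, and 6.31 to 7.64 in the other 11. Hspa1a spanned 8.30 to 587 CPM and Hspa1b 26.6 to 1295 CPM; their coding sequences are almost the same, so reads can be shared between them. The more abundant Hspa8 varied less, from 853 to 1830 CPM. Immediate early genes, which rise within minutes of handling, had a narrower 2.14-fold range, with the highest score, 5.91, in R63500_2.

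All 29 genes of the cholangiocarcinoma driver list were detected above the filter. By median CPM, which is not adjusted for gene length, Ctnnb1 was the most abundant (1419 CPM), followed by Idh1 (338 CPM), Elf3 (324 CPM) and Tgfbr2 (222 CPM). Nras and Hras had medians of 70.0 and 43.1 CPM. Trp53 varied 1.36-fold, from 65.7 to 89.5 CPM. For 21 of the 29 genes the highest library was at most 2-fold above the lowest. The widest ranges belonged to Sox17 (5.13 to 33.6 CPM), Egfr (49.8 CPM in R62850_2 to 209 CPM in R63500_2), Brca2 (1.73 to 7.19 CPM), Cdkn2a (4.02-fold, up to 8.02 CPM) and Myc (12.8 to 48.3 CPM). Gene counts show expression only, so they carry no statement on mutation or deletion.

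**Figure D2:**
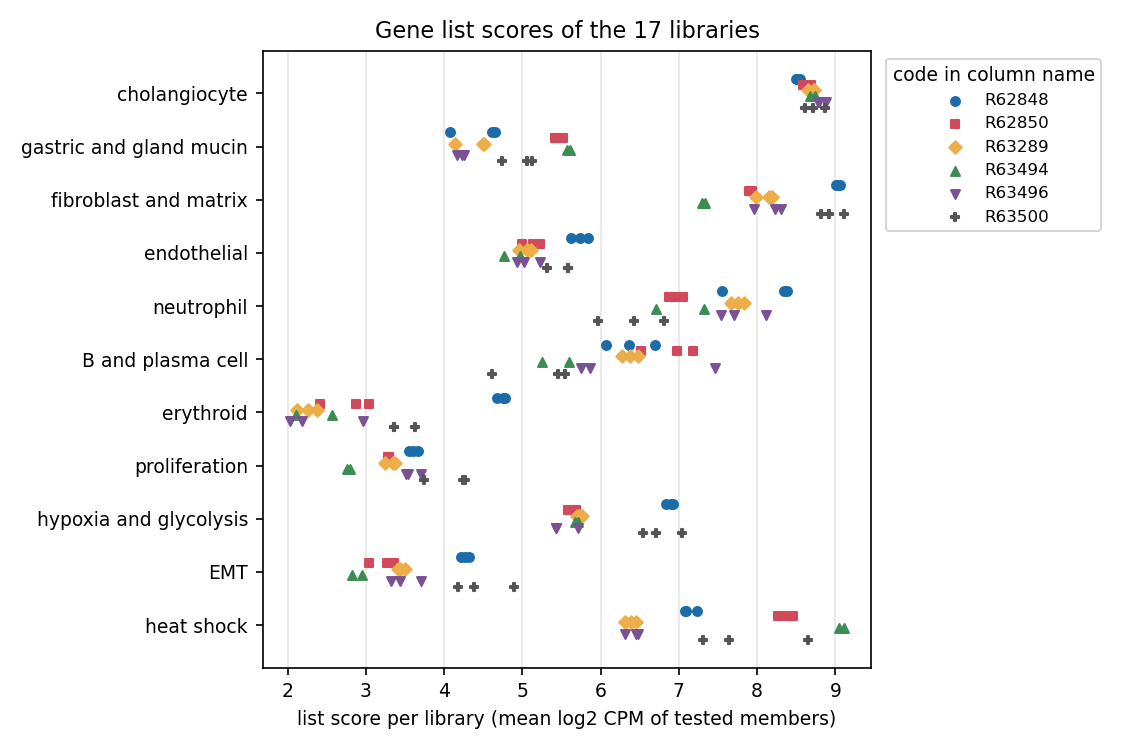
List score of each of the 17 libraries (x axis, mean log2 CPM of the tested members) for 11 gene lists (y axis), with symbols and colours for the code in the library's name. Cholangiocyte scores lie between 8.49 and 8.88, while heat shock scores lie between 6.31 and 9.10 and libraries of a code lie close together in most lists.

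Libraries that shared a code resembled each other. The Pearson correlation of log2 CPM was 0.970 to 0.991 in the 16 pairs within a code and 0.931 to 0.981 in the 120 pairs between codes, and all 17 libraries had their closest library within their own code. The biological coefficient of variation was 26.8% over all libraries and 15.1% within codes. No 2 libraries were identical. The lowest chi-square per degree of freedom of a pair was 3.46, above the 1 that sampling noise alone gives, so no library was counted as another one deposited again. Separate preparations of the same RNA would also exceed 1, but they would not give the acinar enzyme shares of R62850, which differed from 0.618% to 11.96%, nor an immunoglobulin share of 1.89% in R63496_3 beside 0.690% and 0.617% in R63496_1 and R63496_2. R63500_2 stood apart in the same way, with an immunoglobulin share of 0.346% beside 0.777% and 0.853% and a heat shock score of 8.65 beside 7.30 and 7.64. The tables do not settle this for the remaining pairs within codes, since how far separate preparations would differ was not measured. The first principal component of the 500 most variable genes held 38.0% of their variance, the second 18.3% and the third 14.4%. On the first component a mixture of 2 normal distributions described the libraries better than 1 (BIC gain 8.56), and it placed the 6 libraries of R62848 and R63500 apart from the other 11. These sets come from the expression values and are not groups of the study, so they were not tested against each other. The BIC treats the 17 libraries as independent, so resemblance within codes alone can raise its gain, and the sets and the correlations within them rest on it.

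**Figure D3:**
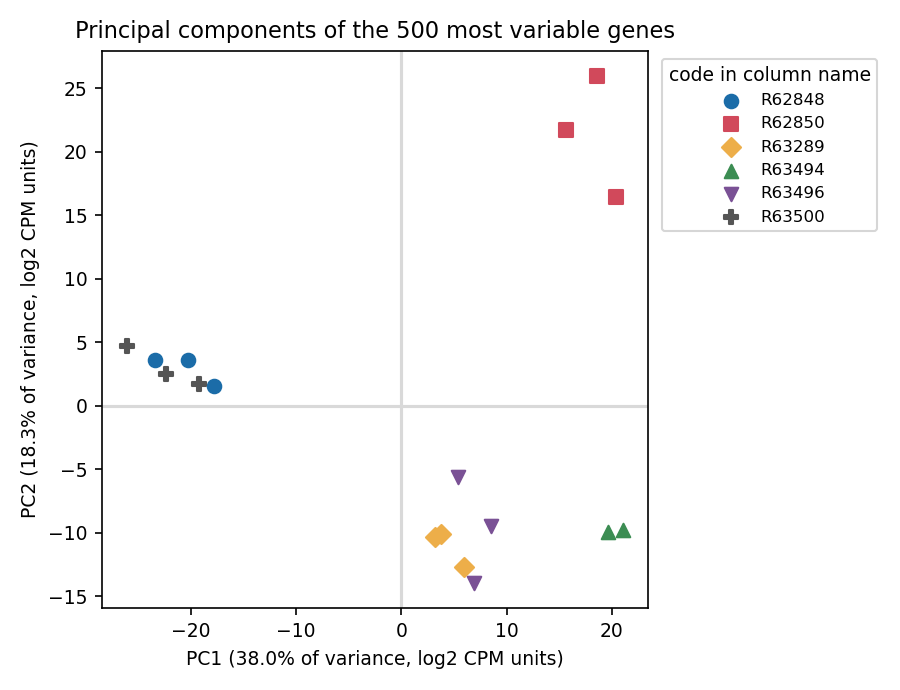
First and second principal components of the 500 most variable genes (log2 CPM units, 38.0% and 18.3% of the variance), with a point per library and a colour and symbol per code. The 6 libraries of R62848 and R63500 lie at negative values of the first component, and the 3 of R62850 have the highest values of the second.

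No gene varied more between the libraries than genes of like abundance in edgeR's quasi-likelihood test (0 of 15795 genes after Benjamini-Hochberg adjustment, 1018 at an unadjusted p under 0.05). The limma-trend version also called 0 genes (994 unadjusted), whereas DESeq2 marked 349 genes as dispersion outliers. In simulated libraries with dispersions as uneven as those measured here, the edgeR test recovered 0% of 200 genes given added variation, so its count of 0 does not show that genes varied alike. Without the expression filter, edgeR called 436 of 29354 genes, among which 109 had their highest count in an R62850 library; with each gene's own prior degrees of freedom, the form of the test first chosen, it called 0 genes (0 unadjusted). With no gene called among the tested genes, no fixed list could be enriched among them. The members of 20 of the 29 scored lists had a median SD at or above the 95th percentile of 10000 random lists matched on expression. Members of 25 lists also correlated with each other at or above that percentile, with the highest mean correlations in the erythroid (0.915), heat shock (0.893), hypoxia and glycolysis (0.802) and fibroblast and matrix (0.733) lists. After code means were subtracted, an alternative chosen after seeing the data, 22 lists remained at or above it, with a mean correlation of 0.792 in the neutrophil list and 0.258 in the fibroblast and matrix list.

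Because the libraries fell into separate sets, no correlation of list scores was computed over all 17. In the set of 11 libraries, 2 of 325 pairs of lists passed the adjusted threshold for both coefficients. Neutrophil and inflammatory cytokine scores had a Pearson r of 0.916 (2-sided permutation p = 5e-05, adjusted p = 0.00975) and a Spearman rho of 0.918 (p = 0.00019, adjusted p = 0.0309), with r = 0.846 without the 2 libraries farthest from the median. Fibroblast and matrix and EMT scores had an r of 0.904 (permutation p = 9e-05, adjusted p = 0.00975) and a rho of 0.918 (p = 0.00017, adjusted p = 0.0309), with r = 0.770 without the 2 farthest. The count of 2 was not stable: it fell to 0 without R62850_1, R62850_3, R63289_1, R63289_2, R63289_3, R63494_2, R63496_2 or R63496_3, to 1 without R63496_1 or with z scores, and to 0 without the expression filter or with a prior count of 0.5. It was 5 with DESeq2 size factors, library totals or a filter of 1 CPM in 9 libraries and 12 with first principal components. These 11 libraries carried 4 codes, and libraries of a code resembled each other, so they are probably not independent and such p-values are then too small. Within codes, as deviations from the code means over 15552 exact orders, neither pair passed: r was 0.483 for neutrophils and cytokines (exact p = 0.202, adjusted p = 0.706) and 0.619 for fibroblasts and EMT (exact p = 0.117, adjusted p = 0.623). There, 1 of 406 pairs passed, EMT with inflammatory cytokines (r = 0.742, exact p = 6.43e-05, adjusted p = 0.0261, and rho = 0.836 with the same p-values, r = 0.752 without the 2 farthest), and it passed in no fit that left out a library, where a single pair can reach an adjusted p of 0.0522 at best, nor without the filter, with z scores, with first principal components or as a partial correlation given library size. A pair simulated with r = 0.999 within codes also missed the threshold (adjusted p = 0.0522). In the set of 6 libraries, from 2 codes, 0 of 351 pairs passed by exact permutation (58 at an unadjusted p under 0.05 for r, smallest adjusted p = 0.0406), but even a perfect rho reached an adjusted p of only 0.0813 there.

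Of the pairs of lists named beforehand, fibroblast and matrix with TGF-beta targets had an r of 0.810 in the set of 11 (permutation p = 0.00174, adjusted p = 0.0479) but a rho of 0.682 (adjusted p = 0.211) and did not pass. Cholangiocyte scores had an r of 0.272 with fibroblast and matrix scores (permutation p = 0.416) and of 0.402 with proliferation scores (p = 0.221) in that set. Proliferation and MAPK output scores had an r of 0.0194 (permutation p = 0.956), which became 0.687 without the 2 farthest libraries. T cell and interferon response scores had an r of -0.399 (permutation p = 0.225). Within codes none of these 5 pairs passed: r was 0.649 for fibroblasts with TGF-beta targets (exact p = 0.0643), 0.299 for cholangiocytes with fibroblasts (0.489), -0.645 for cholangiocytes with proliferation (0.278), -0.633 for proliferation with MAPK output (0.271) and 0.107 for T cells with interferon response (0.719). The smallest adjusted p among them was 0.581, for the rho of 0.652 of the first pair (exact p = 0.0335). The pairs of cholangiocytes with hepatocytes and with gastric and gland mucin could not be given there, since the scores of these 2 partners, like that of heat shock, fell into separate clusters in the set of 11; within codes their r was 0.122 and -0.494 (exact p = 0.495 and 0.0940). The pair with pancreatic acinar genes had no score. Log2 library total, genes detected, the normalization factor and the share of the 10 most abundant genes had 116 relations with list scores within codes, of which none passed (exact permutation, smallest adjusted p = 0.522). At an unadjusted p under 0.05 there were 4, the smallest for library total with bile acid handling (r = -0.747, exact p = 0.0045). Tests within codes have little power, and these relations were not tested in the set of 11, so technical influence there is not excluded.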

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

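Chosen after the data had been seen were all tests between or within codes and the form of the variable-gene test reported here, which takes the largest prior degrees of freedom; the form with each gene's own was written beforehand. The count of variable genes was 0 in the edgeR test (1018 at an unadjusted p under 0.05) and also 0 with limma-trend (994 unadjusted), a non-robust prior (901 unadjusted), the other normalizations, a filter of 1 CPM in 9 libraries, an adjusted p below 0.01 and each library left out. It was 349 by DESeq2's dispersion outliers and 436 without the filter, and with each gene's own prior degrees of freedom it was 0 with the filter (480 unadjusted) and 0 without it (0 unadjusted). The 436 therefore rest on the changed form of the test; 336 of these genes were also tested in the filtered set. Fixed lists enriched among the variable genes numbered 0 with the filter, where no gene was called, 11 without it, and 18 when genes differing between codes took the place of variable genes.

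The count of list pairs that passed in the set of 11 libraries, 2, was 5 with DESeq2 size factors, 5 with library totals, 0 without the filter, 5 with a filter of 1 CPM in 9 libraries, 0 with a prior count of 0.5, 1 with z scores and 12 with first principal components of the members. It was 0 to 2 when a library was left out: 1 without R63496_1, and 0 without R62850_1, R62850_3, R63289_1, R63289_2, R63289_3, R63494_2, R63496_2 or R63496_3. The cause was not tested. Within codes the count of 1 became 0 without the filter, 2 with a prior count of 5, 0 with z scores and 0 with first principal components. It was 0 to 0 with each library left out, where fewer orders (5184 to 7776) keep a single pair at an adjusted p of 0.0522 or above. In 21 alternatives EMT with inflammatory cytokines lost its call, with r between 0.599 and 0.815. No pair passed in the set of 6 under any of 26 alternatives. There a perfect rank correlation, with the smallest p that 720 orders give (0.00278), had an adjusted p of 0.0813 in the main analysis, so these counts of 0 say nothing on stability.

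Coherent lists numbered 22 to 29 (25 in the main analysis), the median range of a list score was 1.32 to 1.48 log2 (1.38), and genes differing between codes numbered 6409 to 8728 (7692). Repeats on the authors' FPKM and a correlation given the mitochondrial share, both chosen before the data were examined, were not run, the first because those columns were not used and the second because mitochondrial genes had no counts. Shares and levels near 1 CPM are limited by totals of 16400556 to 24152314 counts.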

Other observations

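All tests in this part were chosen after the result was seen, except that the prediction on immunoglobulin V genes was written before its values were seen.

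Of 15795 genes, 7692 differed between the 6 codes in the edgeR test (adjusted p below 0.05; 7815 with limma and 8728 with DESeq2). Scores of 26 of the 29 lists differed between codes by permutation, whereas T cell, interferon response and bile acid handling scores did not. Without R62850 the number was 23, as the hepatocyte (adjusted p = 0.0539), B and plasma cell (0.0638) and immediate early (0.0732) scores lost their call. No random lists were scored for this comparison, so the count of 26 cannot be read as particular to these lists. It includes intestinal epithelium, hepatocyte and nerve and Schwann cell scores. The mean correlation of their members stood only at percentiles 70.85, 28.2 and 11.8 of matched random lists. Of the 29 driver genes 19 differed, and 21 when adjusted over the list alone. The 2 R63494 libraries combined the highest heat shock and gastric mucin scores with the lowest fibroblast and matrix scores, and the 3 R62850 libraries were next in gastric mucin (5.41 to 5.52) with heat shock scores of 8.27 to 8.46. R62848 had the highest erythroid scores. In 13 genes the level was at least 1 CPM in every library of some codes with 0 counts in every library of the others, and 5 of these were on the Y chromosome. Most of the rest were acinar-type genes present in R62850, such as Try10 and Cela3a. No code held libraries of both sex-linked patterns, and 5 of the 6188 sets of 5 libraries consist of whole codes (exact p = 0.000808).

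Libraries that shared a code resembled each other, and a candidate explanation is that they come from the same animal or tissue source. Use of 90 immunoglobulin V genes, which differs between B cell populations, correlated at a mean of 0.966 within codes and 0.806 between them (permutation p = 1.0e-05, the smallest the permutations can give), and all 17 libraries had their closest match within their code. V gene usage was set against permuted codes only, not against other sets of genes. Since libraries of a code resembled each other over all genes, this result cannot tell a shared animal from other sources of likeness. These genes carried the biotype IG_V_gene, with 0.0685% of all counts. Genes of the biotype IG_LV_gene, with 0.186%, were left out. Library totals did not follow codes (permutation p = 0.785), and 88.3% of the gap between within-code and between-code correlation remained without 3594 genes that follow the acinar share. Only 1 of 100 divisions of the libraries into sets of these sizes, the real one, gave as many genes as 7692, and the highest other gave 697. Shared preparation of a code's libraries stays open as a contribution. For the sex-linked genes, Xist at 668 to 1499 CPM in 4 codes and at 0.650 to 5.92 CPM in 2 argues against preparation alone. No biological explanation other than a shared animal or tissue source was tested, because the labels give no groups.

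Acinar enzyme genes differed widely among the 3 libraries of R62850, and pancreatic tissue in these samples is a candidate source. The log2 folds of 11 enzyme genes between R62850_3 and R62850_1 ran from 4.23 to 4.59 with an SD of 0.10 (0.0994), as a single source in varying amount would give. The unscaled counts of the enzymes were higher in R62850_3 by 3.95 to 4.30 log2, whereas 15780 other tested genes with a count in both libraries had a median log2 ratio of -0.27 (quartiles -0.48 and -0.05), which argues against normalization or library size. Whether the tissue was taken along with the duct or belonged to the lesion was not tested.

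Heat shock scores differed between codes, and handling of the tissue may contribute. Over the 6 code means, heat shock and immediate early scores had a Spearman rho of 0.0857 (exact p = 0.919), and within codes an r of 0.760 (exact p = 0.0310, adjusted p = 0.488, r = 0.356 without the 2 farthest libraries) and a rho of 0.517 (exact p = 0.106), which neither show nor exclude a link. An earlier form of this test, changed after the scores had been seen, would have counted any rho below 0.5 against handling. Depth is argued against: R63494 and R63289, whose totals overlap (16941092 to 24152314 and 17016507 to 19623222), differed by 2.69 log2, more than the largest range inside a code (1.34). The 5 libraries with Y-linked counts, those of R62850 and R63494, had heat shock scores of 8.27 to 9.10. The other 12 had 6.31 to 7.64, except R63500_2 at 8.65. The sex-linked pattern thus cannot be told apart from other differences between these codes and the rest. No biological explanation was tested.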
